A study of Mus musculus with 16 samples.

How the data were processed

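The series holds 16 one-color Agilent whole mouse genome arrays, 4 on each of 4 slides. Macrophages were sorted by flow cytometry from pancreatic tumors or normal pancreas of mice with a Flt3-driven Cre and a YFP reporter, straight into lysis buffer. Per the labels the mice are female, on a C57/B6 background and 8 to 10 weeks old, and no genotype is given. RNA was extracted with a total RNA kit, amplified with a whole transcriptome kit and labelled chemically with Cy5, so that only the red channel was read. The groups are tumor YFP+ (5 arrays), tumor YFP- (5), normal YFP+ (3) and normal YFP- (3). The number in the sample titles was taken to be the mouse and to pair the samples, which the labels do not state. By it, 5 tumor mice and 3 mice with normal pancreas each gave both populations.

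Per the file headers, the scanner files hold intensity values of the red channel, and the processed signal is background subtracted and spatially detrended, with a surrogate value for spots below the error. The deposited normalized values are on the log2 scale. Its sorted columns are equal between arrays within 0.0069, its median is 9.02 in each, and each column correlates across probes at r = 0.9957 to 0.9999 with the log2 processed signal of its own array, against at most 0.981 with another array (probes are not independent replicates). It therefore holds quantile-normalized log2 processed signal, a step that the sources leave unstated. The intensity values were the starting point here, and the deposited log2 values served as an alternative.

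Each array has 44397 spots, 43020 of them other than controls, for 39429 probes. Spots the scanner software marked as outliers were left out, which left 335 missing probe values, and the spots of a probe were averaged. Genes were named from a RefSeq table of mouse genes by accession (28330 probes), symbol (2204) or synonym (174), and 8721 probes kept the name in the file. Probe positions are those of the file headers, on genome build mm9. The log2 processed signal was scaled by subtracting the 75th percentile of each array over the probes other than controls, so that a value of 0 stands for that percentile. A probe was kept when it was well above background on at least 3 of the 16 arrays, which 30602 were, and 255 of these were left out for a missing value. Of several probes for a gene the brightest was used (4961 genes had several), which gave 24307 genes. Of the 84 entries of named genes 8 had several probes, and 0 had probes of opposite sign.

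Signal over background sets the depth of an array. Between 14.6% and 24.1% of the spots on an array lay at the surrogate value, where differences cannot be read, and 140 to 353 spots were marked as outliers. The median standard error of a log2 difference was 0.27 between the tumor populations, 0.35 between the normal populations, 0.31 between tissues and 0.44 for the interaction. Where the dimmer group of a comparison was below background, the fold is given as at least a value. That value sets the dimmer group no lower than the array's lowest signal well above background. It is a bound under the main background handling only. In tumor the size of the YFP difference over the alternatives was as small as 2.54 for Lum, 0.76 for Tigit and 0.34 for Zfp280b on the log2 scale.

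Genes were tested with limma (lmFit and eBayes) in a model of 4 group means over all 16 arrays, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; the tests are two-sided. The 5 contrasts were YFP+ minus YFP- in tumor, YFP+ minus YFP- in normal pancreas, tumor minus normal pancreas in YFP+ and in YFP- cells, and the difference between the YFP differences of the tissues, called the interaction. For the interaction, groups count as not overlapping when the within-mouse differences of tumor and normal mice do not overlap. The labels state no paired test, so the model without a mouse term came first and the mouse block was an alternative. Within a group, the deviations of both samples of a mouse correlated across genes at r = 0.314, 0.224, 0.0568, -0.188 and -0.290 in the tumor mice. In the others r was 0.274, 0.134 and -0.0154, and the consensus correlation within a mouse was 0.0281. The highest r with the other population of another mouse was 0.460, 0.479, 0.479, 0.374 and 0.460 in the same order of tumor mice. It was -0.0423, 0.247 and 0.247 in the others. These correlations thus do not bear out the pairing, which rests on the numbers alone.

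The 32 gene lists held 981 members, 965 of them on the array. They covered functions of macrophages (presentation by MHC class II and class I, co-stimulation, matrix, matrix remodelling, growth factors, resident and monocyte genes, alternative activation, inflammatory genes, chemokines, interferon targets, complement, scavenger receptors, lipid handling, lysosome, glycolysis, oxidative phosphorylation, proliferation and immediate early genes) and markers of cell types (macrophages, dendritic cells, neutrophils, T and NK cells, B cells, acinar, islet and ductal cells, fibroblasts, endothelium, erythroid cells and mast cells). Each was tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within a contrast, in 160 list tests over the 5 contrasts. Camera with a correlation estimated from the data was an alternative. Members past the threshold were counted over all genes and adjusted over the list alone.

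The genes named are, in each group comparison, the 12 with the highest and the 12 with the lowest log2 difference among those past the threshold that have a gene symbol and whose arrays do not overlap between the groups, 6 in each direction for the interaction, and up to 4 members with the smallest p of each list discussed. The groups, comparisons, tests, lists and this rule were fixed before the data were examined. Some of the genes that the rule names are not reported here.

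The alternatives were another background correction (normexp on the mean spot signal, offset 50), quantile normalization, median scaling, the deposited log2 values, no filter or a stricter filter on dim probes, the mean over the probes of a gene, the mouse as a block (fixed for the YFP contrasts and the interaction, random for the tissue contrasts), the slide as a block, a fit on the compared arrays alone, array weights, a trended and robust variance prior, and leaving out each mouse. Leaving out each single array, and the matrix list without members of the fibroblast list, were chosen after seeing the data. Where only 2 mice remain in a normal group, limma pools the spread over the groups.

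The procedure was tested on simulated data with 200 changed genes per comparison. Of genes changed by 1 on the log2 scale it recovered 36% between the tumor populations, 20% between the normal populations, 32% between tissues and 6% for the interaction, and of genes changed by 2 it recovered 78%, 74%, 62% and 40%. False calls were 6 of 125 calls between the tumor and 7 of 105 between the normal populations. They were 9 of 106 and 5 of 104 between tissues in YFP+ and YFP- cells, and 6 of 52 for the interaction. No slide or mouse effect was simulated. Of 31 unchanged lists 0 were called, but the simulated genes were independent of each other, so the effect of correlated genes on the list test was not examined there.

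The computations used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Control probes were left out, and no array was.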

Results

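RNA was measured in macrophages sorted by flow cytometry from pancreatic tumors and from normal mouse pancreas. The mice carry a Cre recombinase under the control of Flt3, a receptor gene of early blood progenitors, together with a YFP reporter that Cre switches on for good. YFP+ macrophages therefore descend from cells with a history of Flt3 expression, and YFP- macrophages carry no such mark. By the number in the sample titles, taken to be the mouse, each mouse gave both populations. The 5 tumor mice and 3 mice with normal pancreas make 16 arrays in 4 groups: 5 tumor YFP+, 5 tumor YFP-, 3 normal YFP+ and 3 normal YFP-. The series design names wild-type, KPC (a mouse model of pancreatic cancer) and reporter mice, while the treatment protocol speaks of implanted tumors. The labels give no genotype per sample, so the tumor model of these mice is unclear.

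The 75th percentile of the processed signal ran from 2167 to 3388 intensity units per array, and its median from 376 to 660. Between 64.9% and 75.4% of the spots on an array were well above background, and 0 spots were saturated. Within groups, arrays correlated across genes at r = 0.946 to 0.977 in tumor YFP+, 0.908 to 0.964 in tumor YFP-, 0.946 to 0.962 in normal YFP+ and 0.923 to 0.960 in normal YFP- (genes are not independent replicates). The number of arrays limits the precision of each value. After filtering, 24307 genes were tested. Macrophage identity genes, among them the receptor gene Csf1r and the surface marker gene Adgre1, had a mean log2 signal of 3.72 ± 0.19 (SD, n = 5) in tumor YFP+, 3.74 ± 0.20 (n = 5) in tumor YFP-, 3.73 ± 0.17 (n = 3) in normal YFP+ and 3.70 ± 0.44 (n = 3) in normal YFP- samples, relative to each array's 75th percentile.

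**Figure D1:**
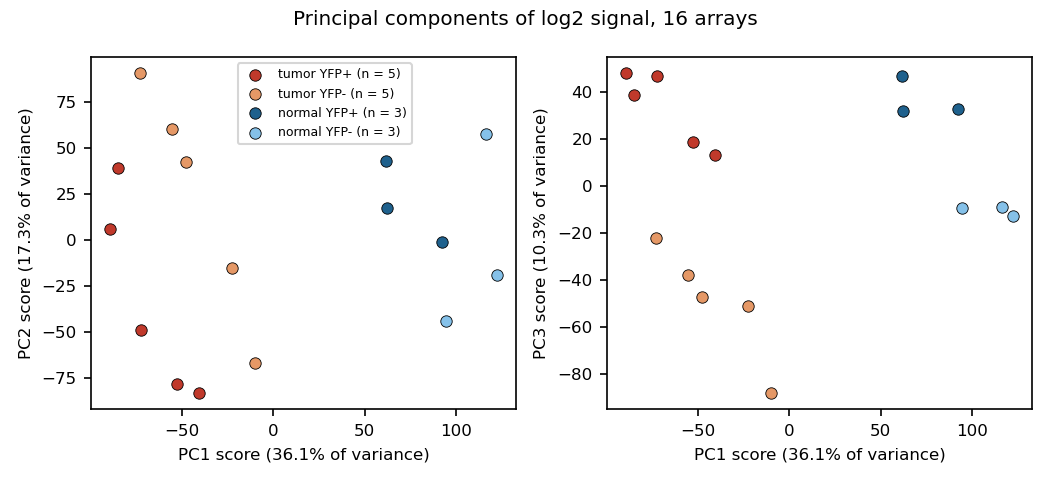
Principal components of the log2 signal of all genes tested, with each point an array and each color a group; the axes are component scores, with the percentage of variance in brackets. The first component (36.1%) parts the tumor arrays, at negative scores, from the normal pancreas arrays, at positive scores, and the second (17.3%) parts the arrays of slides 1 and 2, at positive scores, from those of slides 3 and 4, at negative scores. The third (10.3%) parts YFP+ arrays, at positive scores, from YFP- arrays, at negative scores, in both tissues.

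The comparison of YFP+ with YFP- macrophages in tumors asks how macrophages of different ancestry differ within the same tumor. Tumor YFP+ samples had less RNA of structural matrix genes and more RNA of B cell genes than tumor YFP- samples. Values given for cells are those of the sorted samples, and RNA from other cell types was not excluded for either pattern. Immunoglobulin genes were not tested as a group, and the light chain segments named here are single genes with large differences. Lum, which encodes the collagen-binding proteoglycan lumican, was at least 47.0-fold lower in YFP+ cells (log2 difference -5.60 ± 0.71, SE, n = 5 mice, adjusted p = 5.47e-04). This bound holds under the main background handling, and over the alternatives the size was as small as 2.54 on the log2 scale. The mean log2 signal of Lum was -7.08 ± 0.08 (SD) against -1.47 ± 0.41 in YFP- cells. Igkv4-72, a variable segment of the immunoglobulin kappa light chain, was 32.9-fold higher in YFP+ cells (5.04 ± 0.61, SE, n = 5 mice, adjusted p = 4.40e-04), at 3.77 ± 0.94 (SD) against -1.27 ± 1.45. Serpina3n, a secreted inhibitor of serine proteases, was at least 46.1-fold lower (-5.59 ± 0.36, SE, adjusted p = 1.29e-06), with a size as small as 3.13 over the alternatives. Fcer1a, the alpha chain of the IgE receptor of mast cells and basophils, was lower as well (-5.75 ± 0.81, adjusted p = 0.00109), with a size that depends on the array's floor, since 1 of 5 YFP+ arrays was above background.

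In this comparison 584 genes passed the test, 188 higher and 396 lower in YFP+ cells, and 537 of them differed at least 2-fold. Beside Igkv4-72, the group of the 12 largest increases held the light chain segments Igkv4-53 (log2 difference 4.09 ± 0.72, SE) and Iglv1 (3.39 ± 0.68). It also held 3 genes of antibody-secreting cells. These were the transcription factor gene Bhlha15 (3.74 ± 0.77), Tnfrsf17, which encodes the survival receptor BCMA (2.80 ± 0.45), and Mzb1, an endoplasmic reticulum protein that aids antibody secretion (2.76 ± 0.40). Tnfrsf17 lay at -1.28 in tumor YFP+ and -4.08 in tumor YFP- samples, against -1.61 in normal YFP+ and -0.32 in normal YFP- samples. Its difference is thus a low value in tumor YFP- samples. Mzb1 lay at 1.59 in tumor YFP+ against -3.02 and -2.95 in normal YFP+ and YFP- samples. Bhlha15 is also a member of the acinar list and was above background on 3 of 3 normal YFP- arrays. The others were Tox2 (3.39), Tigit, an inhibitory receptor of T and NK cells (at least 8.72-fold), Tmem72 (2.93), Ak7 (2.89), Zfp280b (at least 6.58-fold) and Nuggc, a germinal center B cell gene (at least 6.34-fold). The group of the 12 largest decreases held the matrix genes Lum, Dcn (decorin, -5.14 ± 0.67), Col6a1 (-5.56 ± 0.88) and Col6a2 (-5.12 ± 0.92), both collagen VI chains. It also held the Wnt pathway modulators Sfrp2 (-5.65 ± 0.92) and Dkk3 (-5.09 ± 0.64). With Fcer1a and Serpina3n, the remaining ones were the cytochrome P450 gene Cyp1b1 (at least 52.8-fold), the netrin receptor gene Unc5b (at least 42.7-fold), the epithelial mucosal glycoprotein gene Dmbt1 (-5.16 ± 0.78) and the scaffold gene Dlg5 (at least 33.4-fold). Over the alternatives the sizes of Cyp1b1, Unc5b and Dlg5 were as small as 2.98, 2.50 and 2.49 on the log2 scale. Of the 12 decreases, Fcer1a and Dkk3 were above background on 1 of 5 YFP+ arrays, Col6a1 and Dmbt1 on 2, and Sfrp2 and Col6a2 on 3. Bhlha15 was above it on 1 of 5 YFP- arrays, Tox2 and Ak7 on 2 and Tnfrsf17 on 3, so the sizes of these differences depend on the floor. Adjusted p-values of the 24 genes ran from 1.29e-06 for Serpina3n to 0.0153 for Bhlha15. On mouse genome build mm9 the probe of Lum lies on chromosome 10, 97035210 to 97035269, and that of Serpina3n on chromosome 12, 105651918 to 105651977. Further positions are chromosome 1, 175151438 to 175151497 for Fcer1a and chromosome 18, 35807187 to 35807246 for Mzb1.

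**Figure D2:**
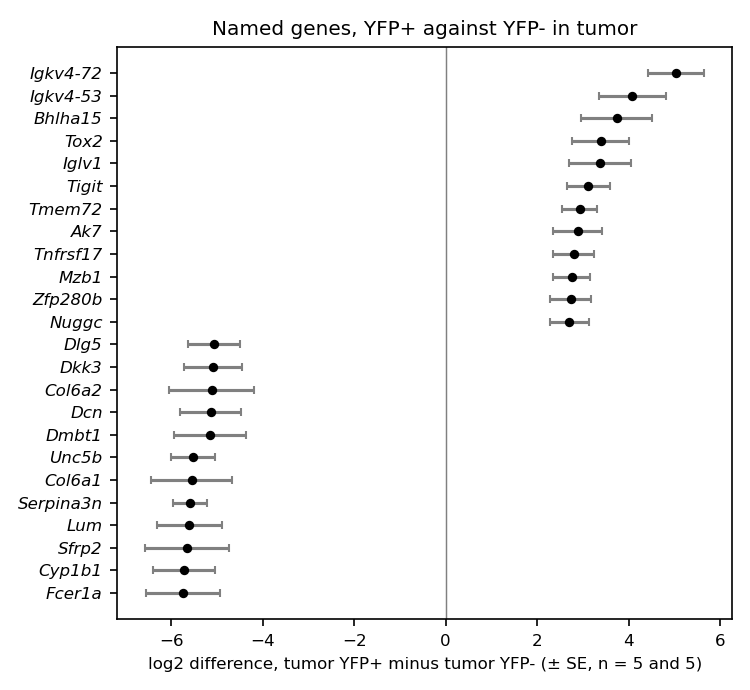
Log2 differences between tumor YFP+ and tumor YFP- macrophages for the 12 largest increases and the 12 largest decreases, with a point per gene and its SE as a bar (n = 5 and 5 arrays). They run from Igkv4-72 (5.04 ± 0.61) at the top to Fcer1a (-5.75 ± 0.81) at the bottom.

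The list of collagens and structural matrix genes fell in tumor YFP+ cells, with 27 of 35 members lower over all genes tested and 28 adjusted over the list alone. Its median log2 difference was -3.03 (camera adjusted p = 1.96e-47 and adjusted p = 0.00919 with an estimated correlation). Examples are Col1a1, a chain of collagen I (-4.38 ± 0.46, SE), Fbln2, a fibulin (-3.47 ± 0.32), Col18a1 (-2.51 ± 0.31) and Thbs2, a thrombospondin (at least 17.9-fold). Fn1, a matrix gene that macrophages express, differed by -0.24 (adjusted p = 0.805). Fibroblast and stellate cell genes fell together with the matrix list, by a median of -1.85 (15 of 30 lower, 19 adjusted over the list alone, adjusted p = 4.77e-25 and adjusted p = 0.00981 with an estimated correlation). Of the 30, 8 also belong to the matrix list. Acta2, smooth muscle actin, differed by -2.97 ± 0.30, and Mgp, the matrix Gla protein gene, by -4.19 ± 0.47. Ductal and tumor epithelial genes fell by a median of -1.49 (14 of 33 lower; 19 lower and 1 higher adjusted over the list alone, adjusted p = 1.20e-18 and adjusted p = 8.37e-04 with an estimated correlation). Among them are the keratins Krt18 (-2.16 ± 0.22) and Krt19 (-3.32 ± 0.41). Mast cell, basophil and eosinophil genes fell by a median of -2.10 (9 of 19 lower, 11 adjusted over the list alone, adjusted p = 1.63e-10 and adjusted p = 0.0281 with an estimated correlation). The protease genes Cpa3 (-4.96 ± 0.91) and Tpsb2 (-2.79 ± 0.42) are examples. B cell genes rose by a median of 0.72 (3 of 24 higher, 6 adjusted over the list alone, adjusted p = 5.26e-10 and adjusted p = 0.0130 with an estimated correlation). The 3 were Mzb1, Fcrla (2.85 ± 0.65) and the B cell coactivator gene Pou2af1 (2.04 ± 0.49), whereas the B cell receptor gene Cd79a (2.07, adjusted p = 0.572) did not pass.

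**Figure D3:**
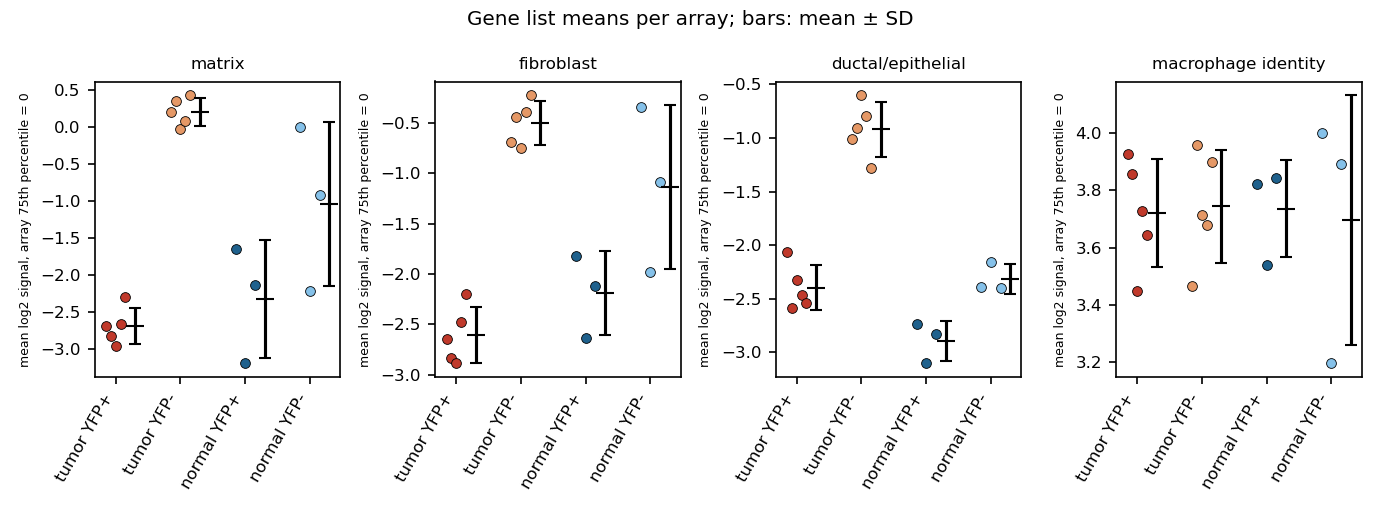
Mean log2 signal of 4 gene lists per array, relative to the array's 75th percentile, with a point per array and the group mean with its SD for each of the 4 groups. Matrix genes average -2.69 ± 0.24 in tumor YFP+ and 0.20 ± 0.19 in tumor YFP- arrays, while macrophage identity genes average 3.72 ± 0.19 and 3.74 ± 0.20.

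MHC class II presentation genes, through which macrophages show antigen to helper T cells, had a median difference of 0.16 in tumor, with 0 of 14 members past the threshold over all genes and 0 adjusted over the list alone. The list test passed at its preset correlation (adjusted p = 0.0412 and adjusted p = 0.323 with an estimated correlation). H2-DMa, which helps load peptides, differed by 0.39 ± 0.13 (SE, adjusted p = 0.221), and the invariant chain gene Cd74 by -0.13 ± 0.15 (adjusted p = 0.859). MHC class I presentation genes had a median of 0.16 with 0 of 14 past the threshold (adjusted p = 0.00862 and adjusted p = 0.337 with an estimated correlation). Flt3 itself, the gene that drives the Cre, differed by 0.27 ± 0.43 (adjusted p = 0.914).

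Other lists passed at the preset correlation and were lost when it was estimated. Markers of fibroblasts and epithelium fell with those that fell, and B cell markers rose, as given above. Matrix remodelling enzymes and inhibitors had a median of -0.23 with 8 of 43 lower, 9 adjusted over the list alone (adjusted p = 3.30e-07 and adjusted p = 0.122 with an estimated correlation). Among the 8 were the collagen cross-linking enzyme gene Lox (at least 28.9-fold) and the inhibitor gene Timp3 (-3.47 ± 0.29, SE). Growth factors acting on fibroblasts and vessels had a median of -0.30 with 3 of 27 lower, 4 adjusted over the list alone (adjusted p = 5.20e-05 and adjusted p = 0.129 with an estimated correlation). The 3 were Ccn2 (-2.48 ± 0.17), Ccn1 (-3.96 ± 0.58) and Tgfb2 (at least 13.6-fold). Tissue-resident macrophage genes had a median of -0.75 with 2 of 31 lower, 3 adjusted over the list alone (adjusted p = 6.43e-07 and adjusted p = 0.332 with an estimated correlation). The pair was Igfbp4 (-1.55 ± 0.34), an insulin-like growth factor binding protein, and the scavenger receptor gene Colec12 (at least 8.87-fold). Complement genes had a median of -0.47 with 3 of 21 lower, 4 adjusted over the list alone (adjusted p = 5.53e-05 and adjusted p = 0.323 with an estimated correlation). The 3 were the C1 inhibitor gene Serping1 (-1.92 ± 0.24), C2 (3.99-fold) and C1s1 (-1.66 ± 0.35). Chemokines had a median of -0.29 with 1 of 27 lower (adjusted p = 0.00862 and adjusted p = 0.276 with an estimated correlation), the neutrophil attractant Cxcl5 (-2.14 ± 0.35). Neutrophil genes had a median of -0.79 with 2 of 26 lower, 5 adjusted over the list alone, adjusted p = 5.71e-07 and adjusted p = 0.0812 with an estimated correlation. Acinar cell genes had a median of -0.57 with 11 of 37 lower and Bhlha15 higher, 16 lower and 1 higher adjusted over the list alone, adjusted p = 1.63e-10 and adjusted p = 0.172 with an estimated correlation. Dendritic cell genes had a median of 0.37 with 1 of 26 higher (adjusted p = 2.70e-05 and adjusted p = 0.311 with an estimated correlation), the transcription factor gene Irf4 (1.18 ± 0.21). Endothelial genes had a median of -0.33 with 1 of 26 lower, 2 adjusted over the list alone, adjusted p = 0.0257 and adjusted p = 0.216 with an estimated correlation.

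The remaining 16 lists did not pass in tumor. Macrophage identity genes had a median of -0.06 (adjusted p = 0.787), monocyte genes -0.05 (0.951), alternative activation genes -0.10 (0.772), and inflammatory cytokines and NF-kB targets 0.02 (0.678). Nfkb2, an NF-kB subunit gene, was the only inflammatory member past the threshold (0.77 ± 0.16, SE, adjusted p = 0.0134). Interferon targets had a median of -0.08 (adjusted p = 0.891), co-stimulation and checkpoint ligands 0.13 (0.737), scavenger receptors -0.10 (0.109, with Colec12 lower), lipid handling genes -0.09 (0.590) and lysosome genes 0.04 (0.460). Glycolysis and hypoxia targets had a median of -0.10 (adjusted p = 0.183), oxidative phosphorylation genes 0.00331 (0.772), proliferation genes 0.03 (0.183), and immediate early and heat shock genes -0.11 (0.0896). With the slide as a block the proliferation median was 0.13 and the list passed (camera adjusted p = 0.0200). T and NK cell genes had a median of 0.18 (adjusted p = 0.227), islet genes -0.17 (0.254) and erythroid genes -0.35 (0.549).

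With the slide as a block, 513 genes passed between the tumor populations. The list medians were -3.07 for matrix, -1.97 for fibroblast, -1.41 for ductal, -1.94 for mast cell, 0.82 for B cell and 0.16 for MHC class II genes. Within the 4 slides the medians ran from -3.53 to -2.95 for matrix, -2.06 to -1.88 for fibroblast, -1.82 to -1.10 for ductal, -1.89 to -1.11 for mast cell, 0.71 to 0.87 for B cell and 0.04 to 0.27 for MHC class II genes. Of the lists that passed at the preset correlation alone, neutrophil, acinar, chemokine, growth factor and MHC class I genes kept their sign on all 4 slides, and 5 others did not. Resident genes gave -0.61, 0.36, -1.25 and -0.79 on slides 1 to 4, complement genes 0.03 and remodelling genes 0.04 on slide 2, dendritic cell genes -0.02 on slide 1 and endothelial genes 0.01 on slide 4. With the mouse as a paired block 599 genes passed. The calls of Bhlha15, Tigit, Ak7, Zfp280b and Nuggc ended with another background correction, and those of Bhlha15 and Iglv1 when single mice were left out. Over the alternatives the log2 difference was as small as 0.76 for Tigit, 0.34 for Zfp280b and 0.60 for Nuggc, below the bounds given above. The count came to 357 without mouse 23550, 379 without mouse 23551 and 374 without mouse 23677. The matrix median was -1.69 with another background correction. MHC class II genes no longer passed with quantile normalization (0.08, adjusted p = 0.210), with the deposited normalized values (0.07, adjusted p = 0.205) or with array weights (0.14, adjusted p = 0.0839). Nor did they pass without any of mice 23548 (0.18, adjusted p = 0.125), 23550 (0.10, adjusted p = 0.0519) and 23677 (0.16, adjusted p = 0.154).

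The same split in normal pancreas asks whether ancestry marks macrophages in the absence of a tumor. In normal pancreas 5 genes passed, 2 higher and 3 lower in YFP+ cells. Cstdc4, a gene of the cystatin family of protease inhibitors, was at least 7.86-fold higher in YFP+ cells (log2 difference 2.97 ± 0.44, SE, n = 3 mice, adjusted p = 0.0400). Fosl1, an AP-1 transcription factor gene, was at least 5.52-fold lower (-2.50 ± 0.36, adjusted p = 0.0386). Also past the threshold were 2 unnamed gene models chosen after their values were seen: Gm9733 at least 8.69-fold higher (adjusted p = 0.0109) and Gm36913 at least 5.38-fold lower (adjusted p = 0.0109). At an unadjusted limma p under 0.05 there were 1858 genes.

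Monocyte and recent monocyte-derived genes rose in normal YFP+ cells, by a median of 0.69 (0 of 27 past the threshold over all genes, 14 higher adjusted over the list alone, adjusted p = 1.42e-14 and adjusted p = 0.0255 with an estimated correlation). Members include the integrin gene Itgax (1.88 ± 0.39, SE, adjusted p = 0.109), the coagulation factor gene F10 (1.68 ± 0.36, adjusted p = 0.110) and S100a6 (0.98 ± 0.22, adjusted p = 0.129). MHC class II genes had a median of 0.35 with 2 of 14 higher adjusted over the list alone (adjusted p = 4.39e-06 and adjusted p = 0.0869 with an estimated correlation). Dendritic cell genes had a median of 0.55 with 6 of 26 higher adjusted over the list alone (adjusted p = 5.60e-07 and adjusted p = 0.219 with an estimated correlation). Matrix genes had a median of -1.35 with 6 of 35 lower and Fn1 higher adjusted over the list alone (adjusted p = 1.47e-11 and adjusted p = 0.209 with an estimated correlation). Fibroblast genes (median -1.32, adjusted p = 8.35e-08 and adjusted p = 0.209 with an estimated correlation) and acinar genes (-0.98, adjusted p = 6.72e-10 and adjusted p = 0.209 with an estimated correlation) lay on the same side. T and NK cell genes had a median of 0.35 with 2 of 32 higher adjusted over the list alone (adjusted p = 9.02e-04 and adjusted p = 0.385 with an estimated correlation). Further lists passed at the preset correlation alone, among them glycolysis and hypoxia targets (0.21, adjusted p = 1.71e-06), proliferation genes (0.24, adjusted p = 1.26e-06) and resident genes (-0.41, adjusted p = 0.00981). For alternative activation, lysosome and macrophage identity genes the medians were -0.02, -0.06 and -0.07. Their means were 0.19, 0.02 and 0.04, and the test pointed up without passing (adjusted p = 0.0774, 0.316 and 0.124).

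Both populations of normal pancreas lie together on slides 2 and 3 alone. Slide 2 holds the YFP+ array of mouse 23912 and the YFP- array of mouse 23917, and slide 3 holds the reverse. Each slide value here is thus 1 array against 1 array of another mouse, so slide and mouse cannot be told apart. The monocyte list median was 0.99 and 0.46 on slides 2 and 3 and 0.66 with the slide as a block, while the matrix list gave -3.25 and 0.08 and -1.29. The slides also differed in sign for dendritic (1.29 and -0.13), T and NK (1.74 and -0.53), acinar (-1.56 and 0.10), proliferation (1.01 and -0.40) and resident genes (-1.41 and 0.74). Fibroblast genes gave -2.44 and -0.02. The slide block left 2 genes, the mouse as a paired block 0, a fit on the 6 normal arrays alone 0, and another background correction 0. With array weights 1157 genes passed, with quantile normalization 16 (81.3% of them higher against 40.0%), with the deposited normalized values 15 (80.0% higher) and with median scaling 4 (2 of them higher). With no filter on dim probes 10 passed, and with a trended and robust variance prior 13. Leaving out mouse 23912 gave 224 genes and leaving out its YFP- array alone 335. The count was 0 without mouse 23548, 1 without mouse 23916 and 3 without either of mice 23550 and 23551. The calls of Cstdc4 and Fosl1 each ended under several of these fits. Over the alternatives their sizes were as small as 1.09 and 0.49 on the log2 scale, below the bounds given above. An exact permutation test on 3 against 3 arrays cannot go below p = 0.1, and a paired one on 3 mice not below p = 0.25.

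Of the genes higher in tumor YFP+ cells, 120 of 188 were also higher in normal YFP+ cells, with a median log2 difference of 0.34 there against 2.88 in tumor. Of those lower in tumor YFP+ cells, 351 of 396 were lower in normal YFP+ cells as well, with medians of -0.73 and -2.44. Of all genes, 40.0% were higher in normal YFP+ cells.

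The test of whether the YFP difference depends on the tissue called 24 genes, 9 with a more positive YFP+ minus YFP- difference in tumor and 15 with a more negative one. Efna5, which encodes an ephrin ligand (interaction -3.99 ± 0.32, SE, n = 5 tumor and 3 normal mice, adjusted p = 8.48e-05), was above background on 5 of 5 tumor YFP- arrays and on 0 arrays of the other 3 groups. The same held for Thbs2 (-3.90 ± 0.40, adjusted p = 7.42e-04), the endothelin receptor gene Ednra (-4.49 ± 0.47, adjusted p = 8.43e-04), Serpina3n (-5.28 ± 0.60, adjusted p = 0.00161) and the complement factor I gene Cfi (-4.35 ± 0.64, adjusted p = 0.0199). Since 3 of the groups lie at background for these genes, the interaction values depend on the array's floor. Above background on 0 of 5 tumor YFP- and 0 of 3 normal YFP+ arrays, P4htm depends on the floor too. P4htm, a prolyl hydroxylase gene (5.22 ± 0.81, adjusted p = 0.0214), and the small GTPase gene Rab25 of epithelial cells (3.402 ± 0.58, adjusted p = 0.0409) had the more positive difference in tumor. Monocyte genes had a more negative difference in tumor (median -0.77, 0 of 27 past the threshold over all genes, 5 adjusted over the list alone, adjusted p = 1.20e-11 and adjusted p = 0.0470 with an estimated correlation). So did ductal and tumor epithelial genes (-0.82, 0 of 33, 9 lower and 1 higher adjusted over the list alone, adjusted p = 1.52e-06 and adjusted p = 0.0470 with an estimated correlation).

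With the slide as a block 9 interaction genes passed, with list medians of -0.68 for monocyte and -0.69 for ductal genes, and with the mouse as a paired block 16. The calls of P4htm, Rab25 and Cfi ended with the slide as a block, those of Rab25 and Cfi with the mouse as a block, and those of P4htm, Serpina3n, Cfi and Efna5 with another background correction. Array weights gave 357 genes, and leaving out a mouse gave from 8 (without 23551) to 43 (without 23912). It was 14 without mouse 23547 and 10 without mouse 23916. The share with a more positive difference was 37.5%, and 64.0% with another background correction.

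The comparisons of tumor with normal pancreas ask what the tumor changes in each population. In YFP+ macrophages from tumors, Arg1, the arginine-degrading enzyme of suppressive macrophages, was 123-fold higher than in normal pancreas (log2 difference 6.94 ± 0.42, SE, n = 5 and 3 mice, adjusted p = 1.19e-07), at 3.06 ± 0.55 (SD) against -3.88 ± 0.55. In YFP- macrophages it was 139-fold higher (7.12 ± 0.42, adjusted p = 7.90e-08). Il1r2, the decoy receptor for interleukin 1, was 174-fold and 243-fold higher in YFP+ and YFP- cells. Pnlip, the lipase of pancreatic acinar cells, was 162-fold lower in tumor YFP+ cells (-7.34 ± 0.32, adjusted p = 5.06e-09) and 147-fold lower in tumor YFP- cells (-7.20 ± 0.32, adjusted p = 8.12e-09).

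In YFP+ cells 2936 genes passed, 1464 higher and 1472 lower in tumor, and in YFP- cells 3830, 1950 higher and 1880 lower. The largest increases in YFP+ cells were Ctsk, the collagen-degrading cathepsin K (7.92 ± 0.99, SE), Il1r2 (7.44 ± 0.53), the serotonin receptor gene Htr7 (at least 158-fold), the mast cell protease gene Mcpt2 (at least 153-fold), Plet1 (7.15 ± 0.20) and Arg1. Further ones were the light chain segments Igkv6-20 (6.62 ± 1.57), Igkv4-53 (6.49 ± 0.84) and Igkv4-72 (6.32 ± 0.71), the metalloprotease gene Adamdec1 (6.48 ± 0.18), the leptin receptor gene Lepr (at least 73.5-fold) and Inhba, a subunit of activin (at least 69.2-fold). In YFP- cells they were Mcpt2 (7.97 ± 0.52), Il1r2 (7.93 ± 0.53), and S100a9 (7.21 ± 1.12) with S100a8 (6.45 ± 1.09), the calprotectin genes of neutrophils and monocytes, and Arg1. Further ones were Cstdc4 (at least 106-fold), Fam71f2 (at least 97.0-fold), Fcer1a (at least 96.5-fold), Mcpt1 (at least 88.8-fold), Plet1 (6.47 ± 0.20), Csta2 (6.45 ± 0.76) and Htr7 (at least 85.3-fold). The probes of Lepr, Htr7, Plet1 and Clps differ: the 3 of Lepr ran from 1.42 to 6.22 on the log2 scale in YFP+ cells. Those of Htr7 gave 3.85 and 7.30 in YFP+ and 2.63 and 6.41 in YFP- cells. Those of Plet1 gave 7.15 and 10.19 in YFP+ and 6.47 and 10.04 in YFP- cells, and those of Clps -9.26 and -7.15 in YFP+ cells. The values of the genes are those of the brightest probe. The call of Igkv6-20 ended without mouse 23912 and without mouse 23917. All 12 largest decreases in YFP+ cells were digestive enzymes or secreted proteins of acinar cells. They ran from Cela2a (-10.72 ± 0.87) and Reg1 (at least 678-fold) through Try4 (-9.19 ± 0.77), Cpb1 (-8.74 ± 0.43), Pnliprp1 (-8.08 ± 0.75), Prss2, Prss1, Spink1, Cela1, Pnlip and Try5 to Clps (-7.15 ± 0.41). Those in YFP- cells included Cela2a (-8.60 ± 0.87), Rnase1 (-8.13 ± 0.67), Cpb1, Cela1, Pnliprp1, Reg1, Pnliprp2, Cel, Pnlip, the zymogen granule gene Sycn (-7.08 ± 0.42) and the kallikrein gene Klk1b5 (-7.04 ± 1.05). Where the dimmer group was above background on part of its arrays alone, as for Ctsk, Igkv6-20 and Igkv4-53 in YFP+ cells, Mcpt2, S100a8, S100a9 and Csta2 in YFP- cells and several acinar genes, the size depends on the floor. Probes of Arg1 lie on chromosome 10, 24636194 to 24636253, of Plet1 on chromosome 9, 50313107 to 50313166, and of Pnlip on chromosome 19, 58755296 to 58755355, on build mm9.

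Acinar cell genes fell in both populations. In YFP+ cells 31 of 37 were lower and Bhlha15 higher (33 lower and 1 higher adjusted over the list alone), with a median of -6.44 (adjusted p = 5.13e-49 and adjusted p = 0.00787 with an estimated correlation). In YFP- cells 34 of 37 were lower (35 adjusted over the list alone), with a median of -5.88 (adjusted p = 3.10e-42 and adjusted p = 0.0102 with an estimated correlation). All 37 acinar genes were above background on every normal YFP- array and 35 on every normal YFP+ array. Islet genes had a median of -0.16 in YFP+ cells (2 of 21 lower, adjusted p = 0.0639) and -1.14 in YFP- cells (5 of 21 lower, 7 adjusted over the list alone, adjusted p = 7.57e-04 and adjusted p = 0.197 with an estimated correlation). With the slide as a block they were -0.70 (adjusted p = 0.0236) and -0.96, so the list passed in both.

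Glycolysis and hypoxia targets rose in both, by a median of 1.60 in YFP+ cells (27 of 32 higher and Pfkfb4 lower, the same counts adjusted over the list alone, adjusted p = 1.28e-26 and adjusted p = 0.00787 with an estimated correlation). In YFP- cells the median was 1.95 (27 higher and 1 lower, again the same counts over the list alone, adjusted p = 1.22e-30 and adjusted p = 0.00870 with an estimated correlation). The glucose transporter gene Slc2a1 differed by 2.93 ± 0.20 (SE) in YFP+ and 3.04 ± 0.20 in YFP- cells, and the lactate transporter gene Slc16a3 by 2.28 ± 0.20 and 3.44 ± 0.20. Acinar RNA moved in the opposite direction to this list in both comparisons, as given above.

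Alternative activation genes rose in YFP- cells, by a median of 0.91 (13 of 29 higher and 4 lower, 15 and 6 adjusted over the list alone, adjusted p = 1.78e-07 and adjusted p = 0.0199 with an estimated correlation). They include Arg1, Il1r2, the chitinase-like gene Chil3 (6.17 ± 0.48, SE) and the transglutaminase gene Tgm2 (2.61 ± 0.20). In YFP+ cells their median was 0.89 (13 higher and 4 lower, 16 and 6 over the list alone, adjusted p = 7.26e-06 and adjusted p = 0.0650 with an estimated correlation). Inflammatory cytokines and NF-kB targets rose in YFP- cells, by 0.88 (16 of 30 higher and 2 lower, 18 and 4 adjusted over the list alone, adjusted p = 5.97e-10 and adjusted p = 0.0326 with an estimated correlation). In YFP+ cells their median was 0.78 (16 higher and 2 lower, 17 and 3 over the list alone, adjusted p = 4.87e-09 and adjusted p = 0.0650 with an estimated correlation). The interleukin genes Il1b (3.81 ± 0.16 in YFP- and 3.09 ± 0.16 in YFP+ cells) and Il1a (4.67 ± 0.32 and 4.82 ± 0.32) are among them. Monocyte genes rose in YFP- cells, by 1.32 (15 of 27 higher and 1 lower, 16 and 1 adjusted over the list alone, adjusted p = 2.68e-09 and adjusted p = 0.0252 with an estimated correlation). The lectin gene Clec4e (5.09 ± 0.43) and the haptoglobin gene Hp (3.97 ± 0.36) are members. In YFP+ cells the monocyte median was 0.30 (adjusted p = 0.0245 and adjusted p = 0.372 with an estimated correlation).

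Markers of other cells moved with these groups in YFP- cells. Neutrophil genes rose by a median of 1.92 (15 of 26 higher, 17 adjusted over the list alone, adjusted p = 2.03e-14 and adjusted p = 0.0119 with an estimated correlation). Mast cell, basophil and eosinophil genes rose by 2.72 (14 of 19 higher, 15 over the list alone, adjusted p = 8.71e-12 and adjusted p = 0.0193 with an estimated correlation). Ductal and tumor epithelial genes rose by 1.05 (14 of 33 higher and 2 lower, 17 and 3 over the list alone, adjusted p = 5.70e-08 and adjusted p = 0.0122 with an estimated correlation). The epithelial members include Cdh1, which encodes E-cadherin (at least 30.9-fold, a bound under the main background handling only), and Krt19 (4.86 ± 0.48, SE). In YFP+ cells these medians were 1.13 for neutrophil genes (adjusted p = 3.09e-07 and adjusted p = 0.0690 with an estimated correlation) and 1.62 for mast cell genes (adjusted p = 4.91e-05 and adjusted p = 0.198 with an estimated correlation). They were 0.20 for ductal genes (adjusted p = 0.0186 and adjusted p = 0.251 with an estimated correlation) and 0.99 for B cell genes (10 of 24 higher and 1 lower, adjusted p = 3.14e-06 and adjusted p = 0.0650 with an estimated correlation). Matrix genes had a median of 1.16 in YFP- cells (10 of 35 higher and 1 lower, adjusted p = 1.72e-07 and adjusted p = 0.214 with an estimated correlation). Their median was -0.47 in YFP+ cells (5 higher and 2 lower, adjusted p = 0.393).

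**Figure D4:**
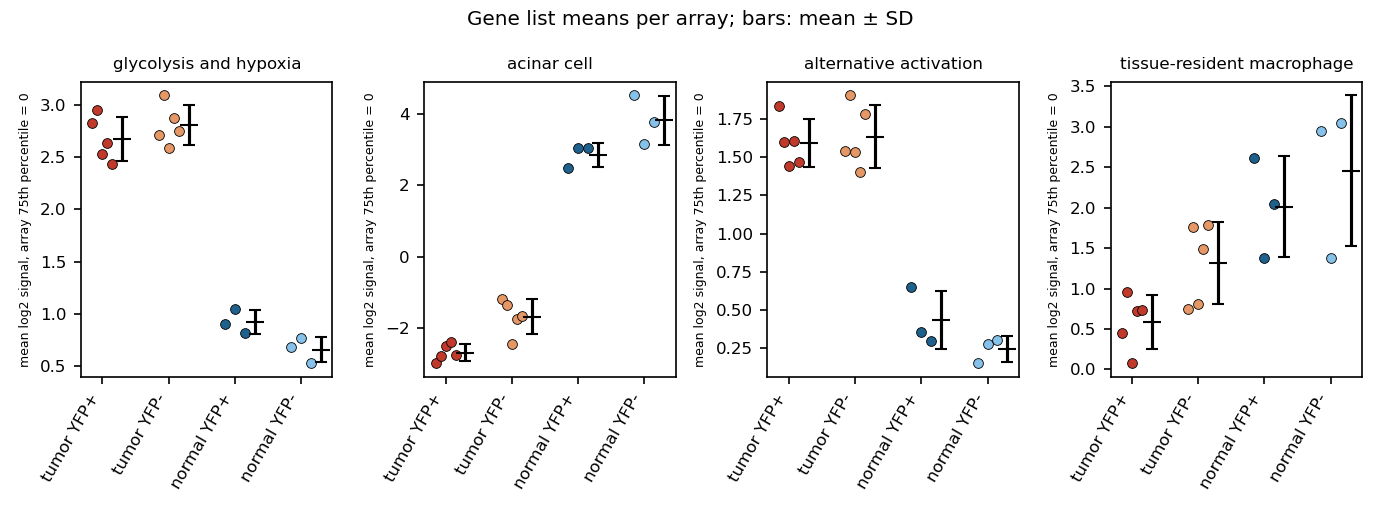
Mean log2 signal of 4 gene lists per array, relative to the array's 75th percentile, with a point per array and the group mean with its SD for each of the 4 groups. Glycolysis and hypoxia targets average 2.68 ± 0.21 and 2.81 ± 0.19 in tumor YFP+ and YFP- arrays against 0.92 ± 0.11 and 0.66 ± 0.12 in normal pancreas, and acinar genes -2.69 ± 0.24 and -1.68 ± 0.49 against 2.86 ± 0.33 and 3.82 ± 0.68.

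The tumor changes overlapped between the populations: 2020 genes passed in both with the same direction, 1091 higher and 929 lower, against 231 if the calls were independent, and 4 passed in opposite directions. The arrays of the comparisons differ, and the mice are the same. With the slide as a block the overlap was 2124 and with the mouse as a random block 2025. It was 3174 with array weights, 1255 without mouse 23916 and 1197 without mouse 23917.

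With the slide as a block 3268 genes passed in YFP+ and 3637 in YFP- cells, and with the mouse as a random block 2954 and 3843. The blocked list medians in YFP+ cells were 1.69 for glycolysis and -6.25 for acinar genes, and slides 1, 2 and 3, which hold both YFP+ groups, gave 1.48 to 1.77 and -6.79 to -6.10. In YFP- cells the blocked medians were -6.15 for acinar, 1.28 for monocyte, 0.89 for alternative activation, 0.74 for inflammatory, 1.84 for neutrophil, 1.12 for ductal and 3.05 for mast cell genes. Slides 2, 3 and 4, which hold both YFP- groups, gave 1.74 to 2.06 for glycolysis, -7.34 to -5.69 for acinar, 0.42 to 1.41 for monocyte, 0.61 to 1.002 for alternative activation, 0.44 to 1.19 for inflammatory, and 1.94 to 3.17 for neutrophil genes. They gave 0.98 to 2.02 for ductal, 1.80 to 3.81 for mast cell and -0.04 to 2.44 for matrix genes. With array weights the counts were 4468 and 9212, a fit on the YFP- arrays alone gave 2264, and without mouse 23917 they were 1903 and 2462, without mouse 23916 1930 and 2222.

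The median over all genes was 0.01 for YFP+ minus YFP- in tumor, -0.10 in normal pancreas, -0.04 and -0.16 for tumor minus normal in YFP+ and YFP- cells, and 0.05 for the interaction. Scaling each array to its median moved these to 0.09 for the tissue difference in YFP+ cells, 0.04 in YFP- cells and 0.04 for the YFP difference in normal pancreas. Another background correction moved them to -0.12 for the YFP difference in tumor, 0.06 for the tissue difference in YFP- cells and -0.08 for the interaction. With median scaling the share of higher genes went from 49.9% to 63.6% in YFP+ and from 50.9% to 66.6% in YFP- cells, and with another background correction to 62.0% in YFP- cells.

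Among called genes, the groups' arrays did not overlap for 517 of 584 in tumor, 5 of 5 in normal pancreas, 2821 of 2936 and 3354 of 3830 between tissues in YFP+ and YFP- cells, and 24 of 24 for the interaction. With 3 against 3 samples chance alone gives such a separation with probability 0.1. The genes Fn1, Pfkfb4, Flt3, Cd74 and Cd79a were chosen after their values were seen. Over all 160 list tests 96 passed at the preset correlation, and 18 held with an estimated correlation: 5 in tumor, 1 in normal pancreas, 2 and 8 between tissues in YFP+ and YFP- cells, and 2 for the interaction.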

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

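The tests for fibroblast RNA, a lower macrophage share, scaling, B or plasma cell RNA and acinar RNA were chosen only after the results they measure were seen.

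The YFP difference depended on the tissue for 24 genes, 7 of them given here. It was more negative in tumor for Serpina3n (-5.28), the endothelin receptor gene Ednra (-4.49), Cfi (-4.35), the ephrin gene Efna5 (-3.99) and Thbs2 (-3.90), and more positive for P4htm (5.22) and Rab25 (3.402), all as log2 differences between the tissues. Another background correction, a slide block or a mouse block ended the calls of P4htm, Rab25, Serpina3n, Cfi and Efna5 in at least 1 case each, while those of Ednra and Thbs2 passed under the alternatives run.

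The YFP difference of 16 lists differed between tumor and normal pancreas at the preset correlation. Monocyte genes (median -0.77, adjusted p = 1.20e-11 and adjusted p = 0.0470 with an estimated correlation) and ductal and tumor epithelial genes (-0.82, adjusted p = 1.52e-06 and adjusted p = 0.0470 with an estimated correlation) passed both ways. The other 14 passed at the preset correlation alone. With the slide as a block the calls of MHC class II, growth factor, chemokine, lipid handling, oxidative phosphorylation, proliferation and islet genes ended. The 14 are given here as median, adjusted p and adjusted p with an estimated correlation. They were matrix genes (-1.61, 7.77e-15, 0.154), mast cell genes (-1.17, 1.70e-07, 0.129), fibroblast genes (-1.06, 1.07e-06, 0.239), neutrophil genes (-1.03, 2.24e-06, 0.153), B cell genes (0.60, 0.00406, 0.276). Further ones were glycolysis and hypoxia targets (-0.37, 5.06e-07, 0.201), islet genes (0.32, 0.0353, 0.533), remodelling genes (-0.31, 0.00122, 0.372), proliferation genes (-0.25, 0.00396, 0.664), MHC class II genes (-0.24, 0.0209, 0.327), chemokines (-0.21, 0.0299, 0.427), lipid handling genes (-0.18, 0.0209, 0.533), oxidative phosphorylation genes (-0.14, 0.00240, 0.631) and growth factors (-0.059, 0.0338, 0.530).

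An array lay far from the other 4 of its group in 10 of 198 groups checked, 8 of them given here, and chance flags about 1 in 20. In tumor YFP+ cells these were mouse 23550 for the complement list (0.57, others 1.02 to 1.13), mouse 23548 for Cel (-3.11, others -2.14 to -1.83), mouse 23547 for Il1r2 (4.47, others 4.86 to 4.91) and Prss1 (-2.89, others -1.69 to -1.36), mouse 23551 for Cpb1 (-5.36, others -4.73 to -4.67) and mouse 23677 for Cstdc4 (0.88, others -0.17 to -0.09). In tumor YFP- cells they were mouse 23548 for Ednra (-3.86, others -2.93 to -2.65) and mouse 23551 for Fam71f2 (1.06, others -0.24 to -0.08).

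Matrix genes were lower in tumor YFP+ than in tumor YFP- samples (median -3.03). Slides are excluded as the whole cause (within-slide median nearest 0: -2.95), as are scaling and background correction (nearest 0: -1.69). A lower share of macrophages in the YFP- samples that raised every other cell type alike would have raised B cell genes there. They were higher in YFP+ samples by 0.723. Since the samples were parted by YFP, which other blood cells can carry too, B cell genes cannot exclude a lower macrophage share as such. Fibroblast, ductal and mast cell genes were all higher in YFP- samples. RNA from fibroblasts may account for the matrix difference. The fibroblast list, written beforehand, had a median of -1.09 without the 8 members that the matrix list also holds. Of the 22 left, 7 were lower (camera adjusted p = 3.00e-12 and adjusted p = 0.0118 with an estimated correlation). That median lies just past a bound of -1, which was chosen after the whole list's -1.85 was seen. The matrix genes with the brightest probes, Sparc, Fn1, Col3a1, Col1a2 and Col1a1, lay at 4.76, 4.63, 4.48, 4.25 and 3.82 in tumor YFP- samples against 0.67, 4.38, 0.61, 0.08 and -0.57 in tumor YFP+ samples, with Vim, the brightest of the fibroblast list, at 5.04 and 4.999, and 20 of the 30 fibroblast genes above background on every tumor YFP+ array. The macrophage sort is meant to remove fibroblasts, but how far it did was not tested. Expression of the matrix genes by YFP- macrophages themselves stays open and untested.

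B cell genes were higher in tumor YFP+ samples. Slides are excluded as the whole cause, with a lowest within-slide median of 0.706. RNA from B or plasma cells and expression by the macrophages cannot be told apart, since the test measured the B cell list (median 0.723), which is the pattern itself. The list's members with the brightest probes were Cd22 (5.11 in tumor YFP+ and 4.70 in tumor YFP- samples), Jchain (4.90 and 2.47), Pou2af1 (3.49 and 1.45) and Xbp1 (3.37 and 2.91), and 18 of the 24 were above background on every tumor YFP- array too. The macrophage sort is meant to remove B cells, but how far it did was not tested. A difference between macrophages of different ancestry stays open and untested.

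Acinar genes were lower in tumor than in normal pancreas in both populations. Slides are excluded as the whole cause, with a within-slide median nearest 0 of -5.69. Acinar RNA carried into all normal pancreas samples may account for it: the acinar list, written beforehand, changed alike in both populations, with an interaction median of 0.239, which a biological change shared by both populations would also give. The digestive enzyme genes Prss2, Prss1 and Cela2a lay at 6.57, 6.41 and 6.14 in normal YFP- and 5.91, 5.92 and 5.32 in normal YFP+ samples, and 26 of the 37 acinar genes were above background on every tumor YFP+ array. The macrophage sort is meant to remove acinar cells but not free RNA or material taken up by macrophages, and neither was tested.

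Other splits of the samples into groups of the same sizes were tried for each count. For the YFP difference in tumor, splits that ignore the mouse gave at most 17 genes against 584, over 100 splits. They exclude chance only if the arrays of a mouse are taken as unrelated. The same limit applies to the matrix list (size of the median 3.03, highest other 2.10). Chance can be excluded for the tissue difference in YFP+ cells (2936, highest other 2) and YFP- cells (3830, highest other 991), over 56 splits each. In each of these 1 split, the real one, gave a result as large. The 16 splits that part every pair of a tumor mouse (highest other 2) are too few to give a share under 0.05. With the pairing kept, the splits therefore cannot exclude chance for the YFP difference in tumor. Splits of whole mice gave at most 2 genes for the interaction (24) and 1 for the overlap of the tissue calls (2020). They mix tumor and normal mice within a group, which widens the spread and leaves few tissue calls to overlap, so they decide neither. Chance cannot be excluded for the MHC class II list (0.158; 0.215), where 6 of 100 splits gave a median as large, nor for the number of list calls (96; 114), where 11 did. The 10 splits of the normal samples are too few to give a share under 0.05 (5 genes; highest other 43, and 5 splits gave as many). The split with 43 genes set both arrays of mouse 23916 and the YFP- array of mouse 23917 against both of mouse 23912 and the YFP+ array of mouse 23917. It divides mouse 23917 and slide 2 and no other mouse or slide, so a structure by mouse or by slide stays open and untested. The paired block of the mouse gave 0 genes there.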

How the results depend on the processing

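Leaving out each single array, and the matrix list without its fibroblast members, were tests chosen after the data were seen. The matrix list in tumor passed with the same direction under every alternative run, with medians from -3.27 to -1.69 and -3.02 without its 8 fibroblast members. The count in tumor stayed between 513 and 806 under the alternatives that keep all mice, and was 357 to 656 with a mouse and 424 to 650 with an array left out (357 without mouse 23550, 379 without 23551, 374 without 23677). The 5 genes in normal pancreas became 0 with normexp, with the mouse as a paired block and on the compared arrays alone, 2 with the slide as a block, 10 with no filter, 13 with a trended and robust prior, 15 with the deposited values, 16 with quantile normalization and 1157 with array weights. They ranged from 0 to 224 with a mouse left out (0 without 23548, 1 without 23916, 3 without 23550 or 23551, 224 without 23912) and from 0 to 335 with an array left out: 0 without normal YFP+ 23916, 3 without tumor YFP+ 23547, 23548, 23550 or 23551, 9 without tumor YFP- 23677 and 335 without normal YFP- 23912. Array weights, from 0.386 to 4.69, gave 4468 genes between tissues in YFP+ and 9212 in YFP- cells, 357 for the interaction and an overlap of 3174, and the compared arrays alone gave 2264 in YFP- cells. With a mouse left out the YFP+ tissue count was 1903 to 2594 (1903 without 23917, 1930 without 23916), and 1958 to 3223 with an array left out. The YFP- tissue count was 2222 to 4572 with a mouse left out (2222 without 23916, 2462 without 23917) and 2394 to 4747 with an array left out, the lowest without normal YFP- 23916. The overlap was 1197 to 1810 with a mouse left out (1197 without 23917, 1255 without 23916) and 1455 to 2123 with an array left out. The interaction count was 9 with the slide as a block and 8 to 43 with a mouse left out (8 without 23551, 10 without 23916, 14 without 23547, 43 without 23912). With an array left out it was 9 to 72: 9 without normal YFP- 23916, 10 without normal YFP+ 23916 or 23917, 11 without normal YFP+ 23912, 12 without tumor YFP+ 23551, 15 without tumor YFP+ 23677 and 72 without normal YFP- 23912. The MHC class II median of 0.16 no longer passed with quantile normalization (0.077), the deposited values (0.073), array weights (0.14) or an estimated correlation (0.16), and its adjusted p ran from 1.75e-04 with normexp to 0.323 over the alternatives that keep all mice. It was 0.10 to 0.22 with a mouse left out and 0.11 to 0.21 with an array left out, and the call ended without mice 23548 (0.18), 23550 (0.10) or 23677 (0.16) and without 6 arrays: tumor YFP+ 23548 (0.17), 23550 (0.11), 23551 (0.12) and 23677 (0.20), and tumor YFP- 23547 (0.17) and 23677 (0.14). The 96 list calls became 18 with an estimated correlation, 91 with the slide as a block and 105 with the mouse as a block, and ranged from 92 to 103 and 93 to 103 with a mouse or an array left out. A few list medians near 0 reversed where the value before or after passed. With a mouse left out (lowest and highest median), YFP+ minus YFP- in tumor ran from -0.087 without 23677 to 0.046 for oxidative phosphorylation. In normal pancreas it ran from -0.019 to 0.098 (without 23917) for alternative activation, -0.055 (without 23912) to 0.18 for lipid handling, -0.13 to 0.064 for lysosome (0.058 without 23917) and -0.23 to 0.068 (without 23917, and 0.043 without 23916) for macrophage identity. Between tissues in YFP- cells it ran from -0.073 (without 23912) to 0.64 for growth factors, -0.094 (without 23912) to 0.29 for lysosome, -0.22 to 0.15 for macrophage identity (0.099 without 23917) and -0.000646 (without 23917) to 0.78 for B cell genes. For the interaction it ran from -0.43 to 0.049 (without 23916, and 0.042 without 23912) for growth factors and -0.10 to 0.13 (without 23912) for lysosome. Other reversals were lysosome between tissues in YFP+ cells (-0.00886 with quantile normalization, -0.0132 with the deposited values) and in YFP- cells (-0.033 with array weights), and for the interaction growth factors (0.033 with array weights) and islet genes (-0.047 with normexp). Of the other 158 list tests 138 kept their side of the threshold, and where they passed their direction, with array weights, 140 with normexp, 81 with an estimated correlation, 143 with quantile normalization, the deposited values or the mouse as a block, 145 with the slide as a block and 148 to 157 under the remaining alternatives that keep all mice. On the compared arrays alone 122 of 126 did, and 1154 of 1264 values with a mouse left out. Of the 84 named genes 70 kept their call with normexp, 77 with the mouse and 79 with the slide as a block, and 72 of 75 on the compared arrays alone. The fit on the compared arrays alone could not be made for the interaction, nor therefore for the number of list calls, and the stricter filter removed 1 named gene. Apart from fits on fewer arrays, which have less to estimate the spread from, the cause was not tested. Signal over background limits the dim genes: 101 of the 584 genes in tumor and 5 of 5 in normal pancreas have a group below background, where another background correction moves the difference.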

Other observations

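The Y-linked and Xist probes were chosen after the data were seen, and the other tests named here were planned.

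Beyond the gene groups of the report, several lists differed between tumor and normal pancreas with the same sign in both populations at the preset correlation. None of them passed with an estimated correlation, and chance was not excluded for the number of list calls, as given above. Tissue-resident macrophage genes had a median log2 difference between tumor and normal pancreas of -1.22 in YFP+ cells (15 of 31 lower and 1 higher, adjusted p = 3.53e-07 and adjusted p = 0.289 with an estimated correlation). The median was -1.06 in YFP- cells (14 lower and 2 higher, adjusted p = 1.70e-04 and adjusted p = 0.368 with an estimated correlation). Among them are the lectin receptor gene Cd209f (-4.41 ± 0.52, SE, and -4.10 ± 0.52) and Maf, a transcription factor gene of resident macrophages (-2.19 ± 0.27 and -2.08 ± 0.27). Within slides the resident list ran from -2.32 to -0.71 in YFP+ and -2.04 to -0.24 in YFP- cells. Interferon targets had medians of -0.62 (10 of 39 lower and 1 higher, adjusted p = 6.74e-05 and adjusted p = 0.251 with an estimated correlation) and -0.66 (11 lower and 1 higher, adjusted p = 8.85e-05 and adjusted p = 0.197 with an estimated correlation). The antiviral gene Oas2 differed by -2.59 ± 0.35 and -3.23 ± 0.35. Matrix remodelling genes had medians of 0.17 (12 of 43 higher and 3 lower, adjusted p = 4.71e-04 and adjusted p = 0.261 with an estimated correlation) in YFP+ cells, and 0.07 with the slide as a block. In YFP- cells the median was 0.56 (17 higher and 2 lower, adjusted p = 5.21e-09 and adjusted p = 0.0534 with an estimated correlation). The membrane-bound metalloprotease gene Mmp14 differed by 3.41 ± 0.23 in YFP+ and 3.53 ± 0.23 in YFP- cells. Markers of acinar cells, neutrophils, mast cells, B cells and epithelium moved in the same comparisons in both populations at the preset correlation.

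The lists of mitochondrial respiration and cell division had positive medians between tumor and normal pancreas, and neither passed with an estimated correlation. Oxidative phosphorylation genes had medians of 0.36 in YFP+ (9 of 49 higher, adjusted p = 6.14e-10 and adjusted p = 0.251 with an estimated correlation) and 0.47 in YFP- cells (25 higher, adjusted p = 1.16e-14 and adjusted p = 0.0976 with an estimated correlation). The cytochrome c gene Cycs differed by 0.85 ± 0.18 (SE) and 1.25 ± 0.18. Proliferation genes had medians of 0.67 (7 of 45 higher, adjusted p = 2.22e-07 and adjusted p = 0.335 with an estimated correlation) and 0.97 (16 higher, adjusted p = 1.34e-11 and adjusted p = 0.197 with an estimated correlation). The division marker gene Mki67 differed by 1.35 ± 0.25 in YFP- cells, but on slide 3 the YFP- median was -0.03. Lipid handling genes had medians of 0.58 (10 of 34 higher and 2 lower, adjusted p = 2.80e-04 and adjusted p = 0.251 with an estimated correlation) and 0.68 (13 higher and 2 lower, adjusted p = 2.11e-06 and adjusted p = 0.0976 with an estimated correlation). The desaturase gene Scd2 differed by 2.33 ± 0.28 in YFP+ and the tetraspanin gene Cd9 by 2.45 ± 0.22 in YFP- cells. Co-stimulation and checkpoint ligands had medians of 0.66 (6 of 14 higher and 2 lower, adjusted p = 0.00815 and adjusted p = 0.251 with an estimated correlation) and 0.99 (6 higher and 1 lower, adjusted p = 0.00129 and adjusted p = 0.0976 with an estimated correlation). Cd274, which encodes PD-L1, differed by 1.92 ± 0.26 in YFP+ cells. Macrophage identity genes had medians of 0.04 (mean -0.01, adjusted p = 0.877) and -0.00221 (mean 0.05, adjusted p = 0.286), and the list test pointed up in both.

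The labels give all mice as female. Probes of the Y-linked genes Ddx3y (log2 signal -2.08 to -0.76), Eif2s3y (0.06 to 1.73) and Kdm5d (-4.54 to -2.49) were well above background on 16 of 16 arrays, those of Uty on 0 and 10 of 16, and those of Xist on 0 and 14 of 16. The signal of Ddx3y, Eif2s3y and Kdm5d argues against the female label. The Xist probes ran from -7.18 to -5.22 and from -4.87 to -0.33. The brighter one lay at a median percentile of 48.0 among the probes of an array, against 81.6 for Eif2s3y, and gives the label no clear support. What else these probes may bind was not tested, so the sex of the mice is unclear.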
